A study of Rattus norvegicus with 64 samples.

How the data were processed

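Chromatin immunoprecipitation followed by hybridization to tiled arrays (ChIP-chip) was measured in fetal rat testes at gestational day (GD) 15 and 19, after maternal treatment with vehicle (control) or di-n-butyl phthalate (DBP). Antibodies against SF1, CBP, PPARA and RNA polymerase II (PolII) were used, with 4 arrays for each antibody, day and treatment, which makes 16 groups and 64 arrays. Per the labels, testes of 4 litters were pooled for each chromatin sample, DNA was amplified before labelling, immunoprecipitated DNA carried the red dye and input DNA the green dye of the same array.

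The scanner files hold, per the file headers, an intensity in each channel that Agilent Feature Extraction 9.5.3.1 had background-subtracted, detrended and scaled between the dyes within the array; the processing notes name version 8.5.1.1. The deposited value table holds a log10 ratio of red to green signal, and its array medians ran from -0.157 to 0.061. Taken in row order, it equalled the ratio in the scanner files at a tolerance of 0.006. Matched by row ID, it agreed in 0.71% to 2.53% of cases per array, with the row IDs shifted by 3 to 4 against the spot numbers. Per the file headers the scale within each array was set by the scanner software, and the deposited values carry no scaling between arrays, so an absolute level of occupancy cannot be read from them. The deposited intensities were converted here to a log2 ratio of immunoprecipitated to input signal, so that a positive value means a higher ratio of immunoprecipitated to input DNA than at the array's median probe.

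Each array carried 15133 genomic spots for 12973 probes on the rn4 assembly. Spots that the scanner software marked as outliers were dropped (26 to 166 per array), spots of 1 probe were averaged, and each array was centred on its median; the medians taken away ran from -0.526 to 0.218. A gene's value is the mean of all its probes. This gave 227 genes with at least 4 probes each (median 57), while 239 probes with no gene in the files entered the probe tests only. Input signal stood well above background at 98.99% to 100% of spots per array and immunoprecipitated signal at 90.4% to 99.95%; for arrays, the number of arrays limits the precision. Array 3 of the PolII GD15 DBP group repeated array 2 within spot noise (r = 0.966 across probes), so their mean was used as 1 sample, which left 63 samples and 3 in that group.

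Groups were taken from the labels. DBP was compared with control for each antibody and day with limma 3.58.1 (moderated, two-sided tests, R 4.3.3, data.table version 1.17.8), once over genes and once over probes, with Benjamini-Hochberg adjustment within each comparison and a threshold of 0.05. The difference in DBP effect between the days was tested as an interaction for each antibody. Enrichment in control arrays asked for a gene mean of at least 0.5 above the array median at an adjusted p below 0.05. Gene lists (7 lists, 56 tests) were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation, and with fry. Marker lists of germ cells, peritubular myoid cells, stroma and vessels, and blood and macrophages had 0 genes on the array; the adrenal cortex list had 1 (Cyp21a1) and the list of genes of other tissues had 2 (Apoa2 and Ttr). Single values per array were compared by exact permutation tests, two-sided, or with 100000 resamples where 10 or more values stood in a group. Plots were drawn with matplotlib 3.10.9 under Python 3.11.15.

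Genes were named by a rule that, like the groups, tests, lists and most alternative settings, was fixed before the data were examined. It names a panel of 18 genes (10 were on the array), the 3 largest rises and falls past the threshold in each comparison or the 3 smallest p-values where fewer pass, the 3 highest genes in the controls of each antibody and day, the 3 smallest interaction p-values for each antibody, and the probes of smallest p. Genes known in the files only by a sequence identifier are counted but not named, and some results that the rule selects are not reported here.

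The procedure was tested on simulated data with 40 of 227 genes shifted. A shift of 1 log2 unit was recovered in 72.5% to 97.5% of the genes over the 8 comparisons and a shift of 2 units in 97.5% to 100%; a shift of 0.5 units was recovered in 0% to 62.5%. Single probes shifted by 2 units were recovered in 0% to 47% of cases and by 4 units in 50% to 84%. Interactions of 1 unit were recovered in 52.5% to 85% of genes. The simulated noise was normal and independent between genes and between probes, with 1 spread for all groups compared and no shift of whole arrays. The real arrays differ in these respects, and where fewer genes change the adjustment is stricter, so recovery in the real data may be lower.

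Alternative settings chosen at the same time were another background correction (normexp, offset 50), loess within arrays, a common spread of all arrays, a filter on dim probes, the deposited ratios, a single fit of all arrays, a block for the replicate number, a window of 3 probes for each gene, the immunoprecipitated channel alone, and each replicate left out in turn. Alternatives chosen after seeing the data were the probes near transcription starts alone, the omission of probes whose input differed between treatments, array weights, the omission of arrays with low immunoprecipitated signal, and both arrays of the repeated pair as separate samples. Replicate numbers gave no sign of a pairing of control with DBP arrays: at most 1 of 4 same-numbered pairs in any comparison correlated above 0.1. Values this noisy cannot exclude a pairing. Slides held 1 antibody and 1 day each, with control arrays in one row and DBP arrays in the other, and each day was scanned on its own date, so position on the slide cannot be told apart from treatment, nor scan date from day.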

Results

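The data describe the occupancy of 227 rat genes by the nuclear receptors SF1 and PPARA, the acetyltransferase CBP and RNA polymerase II in fetal testes at GD15 and GD19, with and without DBP, a phthalate plasticiser that lowers steroid output of the fetal rat testis. SF1 drives transcription of steroidogenic genes, CBP is a coactivator recruited by many transcription factors, and PPARA is a fatty acid sensing receptor that phthalate metabolites can activate. Each of the 16 groups had 4 arrays, counted as 3 samples for PolII in GD15 DBP testes. Median signal per array ran from 572 to 867.7 in the input channel and from 473.3 to 932.4 in the immunoprecipitated channel. The tiles formed 201 regions with a median length of 7296 bp, and they covered the transcription start (a probe within 500 bp) of 116 genes. For 111 genes the start was not covered, among them Star, whose 15 probes lay 4971 to 6312 bp downstream of the start, and Cyp17a1, whose 83 probes lay 4025 to 11248 bp downstream.

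Replicate arrays of a group agreed weakly. The log2 ratios of all probes correlated between replicates with a median r of 0.16 (range 0.08 to 0.63, 95 pairs), against 0.13 between control and DBP arrays of the same antibody and day and 0.12 between different antibodies of the same day and treatment. The 4 SF1 arrays of GD15 DBP testes were the most alike, with a median r of 0.45. Input DNA alone correlated at 0.99 between replicates and immunoprecipitated DNA alone at 0.69. These are correlations across probes, which are not independent replicates.

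**Figure D1:**
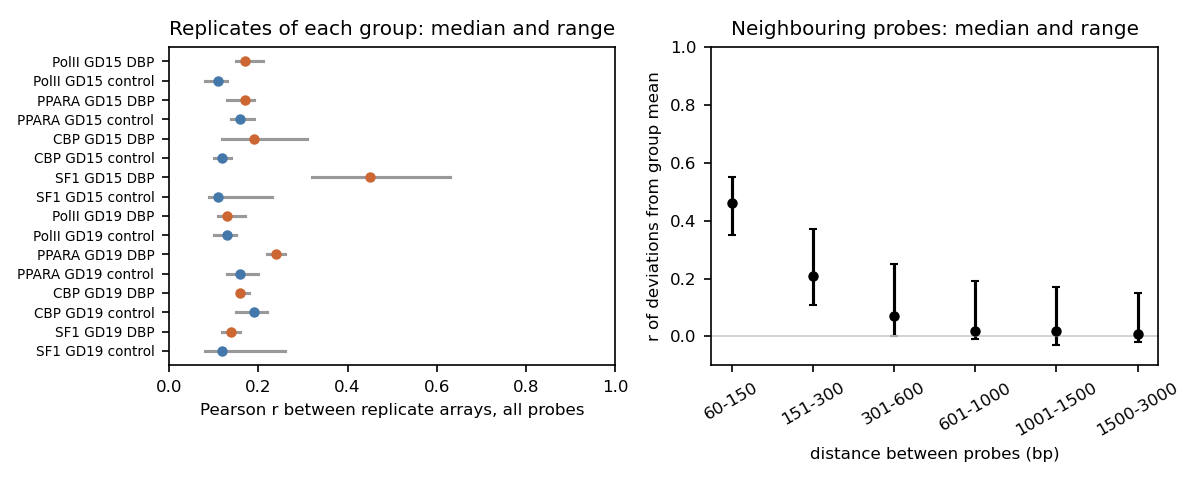
Left, Pearson r of log2 ratios across probes between replicate arrays of each group (point, median; line, range; blue, control; orange, DBP). Right, correlation of each sample's deviations from its group mean between probes at the distances shown (point, median over samples; bar, range); it is 0.46 at 60 to 150 bp and 0.01 at 1500 to 3000 bp.

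In control testes, the genes with signal above the rest of the array were few. PPARA arrays at GD15 had 3 of them: B3gnt3_predicted at 0.78 ± 0.35, Eef2, which encodes the ribosomal elongation factor, at 0.65 ± 0.37, and 1 gene known only by a sequence identifier at 0.61 ± 0.28 (SD, n = 4 each). Eef2 was tiled with 18 probes over chromosome 7, 10017062 to 10019359, inside the gene.

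By limma, enrichment in controls passed at an adjusted p of 0.0124 for B3gnt3_predicted and 0.0371 for Eef2. In 6 other antibody and day groups 0 genes passed; at unadjusted p below 0.05 the numbers above the median by 0.5 were 8 for SF1 at GD15, 0 for CBP at GD15, 0 for PolII at GD15, 0 for SF1 at GD19, 0 for CBP at GD19 and 1 for PPARA at GD19. Among those without a pass were Ccdc45 (0.79 ± 0.84) and Brd2 (0.66 ± 0.68) on SF1 arrays at GD15 (SD, n = 4). On the same arrays known SF1 target genes stood at 0.31 ± 0.73 for Star, -0.29 ± 0.32 for Cyp11a1 (side-chain cleavage enzyme), 0.08 ± 0.25 for Scarb1 (lipoprotein receptor), -0.12 ± 0.16 for Inha (inhibin alpha) and -0.44 ± 0.15 for Nr0b1 (a repressor of SF1), which stood below the median (unadjusted p = 0.0226, limma adjusted p = 0.243). By limma, genes at least 0.5 below the median numbered 25 with PPARA at GD15, with Atp6ap1 lowest (-1.49), and 20 with PPARA at GD19. With PolII they numbered 5 at GD15 and 1 at GD19 (Prkar2b, -1.0). Atp6ap1 and Prkar2b were chosen after their values were seen. Over all control and DBP samples Atp6ap1 averaged -0.28 with SF1, -0.31 with CBP, -0.86 with PPARA and -0.39 with PolII. Prkar2b averaged -0.20, -0.26, -0.54 and -0.39, so both were low with every antibody. Gene means lay mostly below the array median (the gene ranked 114 of 227 averaged -0.13 over all samples), which favours low calls over high ones. PPARA enrichment ended when control replicate 1 was left out (0 genes) and under the normexp background correction (0 genes).

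PPARA signal was higher near transcription starts than elsewhere in the tiles. In control arrays the difference between probes near starts and all other probes was 0.21 ± 0.06 log2 units for PPARA (SD, n = 8) and 0.04 ± 0.08 for the other antibodies (n = 24), and it was above 0 in 8 of 8 PPARA arrays. The two-sided permutation p was 5e-05 (100000 resamples). This test counts arrays as independent, although PPARA stood on 2 slides and the other antibodies on 6, so the p may be too small. Within the days it was 0.26 ± 0.04 at GD15 and 0.16 ± 0.04 at GD19 (n = 4 each). Probes near starts were also richer in G and C (47% against 41.1%), and after matching for that content the PPARA control difference was 0.01 ± 0.04 at GD15 and -0.07 ± 0.07 at GD19. With DBP the difference was 0.13 ± 0.12 at GD15 and 0.32 ± 0.16 at GD19 (n = 4 each); each day's exact two-sided permutation p against control was 0.0286, the smallest that 4 against 4 samples allow, and 0.114 after adjustment over the 8 comparisons. After matching for G and C content the DBP values were -0.03 ± 0.09 and -0.01 ± 0.11. At GD19 DBP arrays 3 and 4, of low immunoprecipitated signal, stood at 0.35 and 0.53 before matching and arrays 1 and 2 at 0.21 and 0.19.

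PPARA at GD15 was the comparison in which genes passed the test, and it asks whether DBP alters PPARA occupancy early in testis development. B3gnt3_predicted fell by 1.21 log2 units (SE 0.21), from 0.78 ± 0.35 in control to -0.43 ± 0.03 in DBP testes (SD, n = 4 each). Its 4 probes lie on chromosome 16, 18891909 to 18892100, directly beyond the tile of Insl3 and 9838 to 9977 bp downstream of the start assigned to B3gnt3_predicted. Zswim3_predicted rose by 1.30 (SE 0.28), from -0.99 ± 0.53 to 0.31 ± 0.38 (n = 4 each). Its 7 probes lie on chromosome 3, 155829748 to 155830164, at -9985 to -9615 bp from its start. In both genes the immunoprecipitated channel carried the difference (-1.04 and 1.29) and the input channel did not (0.14 and -0.04). Both rest on few probes, against a median of 57 per gene. With PPARA at GD19, B3gnt3_predicted varied more, with an SD of 1.11 in control and 1.28 in DBP testes.

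The limma adjusted p was 0.0135 for B3gnt3_predicted and 0.0417 for Zswim3_predicted, 2 of 227 genes, with 21 at unadjusted p below 0.05. Slco1b2, an organic anion transporter, came next at 0.95 (adjusted p = 0.184). Of 12950 probes 0 passed by limma, with 875 at unadjusted p below 0.05; those of smallest p lay upstream of the proteasome gene Psma6 (4.84, adjusted p = 0.0721) and of Als2cr13 (3.34, adjusted p = 0.0721). With the immunoprecipitated channel alone 0 genes passed, at adjusted p = 0.0501 for B3gnt3_predicted and 0.0715 for Zswim3_predicted, and 0 genes passed without control replicate 3 or without DBP replicate 3. In 1 fit of all arrays both calls ended (adjusted p = 0.106 each) and 2 other genes passed. Zswim3_predicted also lost its call with the window of 3 probes (adjusted p = 0.371), with a common spread of the arrays (0.0513), with array weights (0.061), and without control replicate 1 (adjusted p = 0.242), control replicate 2 (0.131), DBP replicate 2 (0.0587) or DBP replicate 4 (0.145).

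**Figure D2:**
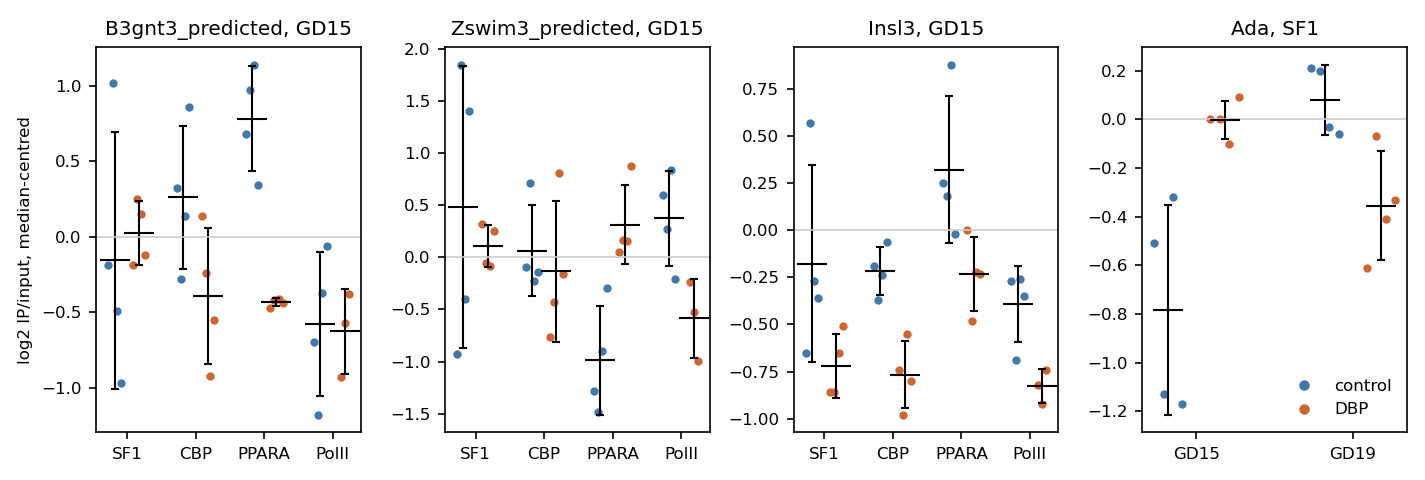
Median-centred log2 ratio of immunoprecipitated to input DNA per sample (points; bar and whiskers, mean and SD; blue, control; orange, DBP) for 3 genes at GD15 by antibody, and for Ada with SF1 at both days. With PPARA, all 4 DBP samples of B3gnt3_predicted lie below and all 4 of Zswim3_predicted above the control samples.

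SF1 at GD15 showed differences at single probes rather than over genes. Probes with higher ratios in DBP testes belonged to 21 genes, and Lmo4, a LIM-domain transcription cofactor, held 5 of them within chromosome 2, 242499248 to 242499653. Other rises were at Acot2, a mitochondrial acyl-CoA thioesterase (4.36, at -176 bp from the start), Inha (3.89, at -3970 bp) and Hmgcs1, of cholesterol synthesis (2.44). Ratios fell at 3 probes of Prdx2, a peroxide-reducing enzyme (-7.06, -5.53 and -5.20; chromosome 19, 24836508 to 24836717), and at probes of Cyp4a10 and Cpt1b of fatty acid metabolism (-3.36, -3.13 and -2.63), of the transporter Abcg2, of Klk1b3 and of Mlycd. The rising probes averaged -2.58 in control and 0.42 in DBP arrays, and 24 of the 25 stood below -1.5 in controls.

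By limma 25 probes rose and 10 fell, out of 12971, and the largest fall had an adjusted p of 0.00308. All 10 falling probes were among those whose input DNA was more than 1 log2 unit higher in DBP than in control arrays, and 0 of the 25 rising ones were. At the Prdx2 stretch immunoprecipitated DNA with SF1 also fell, from 2.83 ± 0.81 to 0.84 ± 0.54 (SD, n = 4 each). At the gene level 0 of 227 passed by limma, with 24 at unadjusted p below 0.05 (16 higher, 8 lower); the smallest p-values were those of Ada, adenosine deaminase (0.78, control -0.78 ± 0.43, DBP 0.00 ± 0.08), MGC94192 (-0.77) and Prdx2 (-0.87), each with an adjusted p of 0.457. The log2 ratios also had a narrower spread on the DBP arrays, with an SD of 0.67 ± 0.11 against 1.23 ± 0.34 in control, at an exact two-sided permutation p of 0.0286 (the smallest possible) and 0.114 after adjustment over the 8 comparisons. The immunoprecipitated channel alone gave 8 probes, all higher, and without the probes of changed input 7 passed, all higher. The normexp correction gave 1 higher and 22 lower, the replicate block 0 higher and 2 lower, and array weights 45 higher and 26 lower. Leaving out 1 replicate gave 3 probes (DBP 2 or DBP 3), 4 (DBP 4), 6 (DBP 1), 18 (control 2), 58 (control 4) or 147 (control 3).

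CBP at GD15 differed at 5 probes. Ratios rose at a probe of Creb1, whose phosphorylated product recruits CBP (3.56, at -624 bp from the start), and at a probe of Pparg, the adipogenic nuclear receptor (3.35, at 480 bp). They fell at 2 probes of Prdx2 (-4.48 and -3.56) and at 1 of Mlycd, malonyl-CoA decarboxylase (-4.61). The 2 rising probes averaged -2.61 in control and 0.84 in DBP arrays, and both stood below -1.5 in controls. At the gene level the smallest p-values belonged to Eif1a, a translation initiation factor (0.82), Insl3 (-0.55) and Rab11a, a recycling endosome GTPase (0.60).

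By limma the Prdx2 probes passed at adjusted p = 0.00299 and 0.0126, and the other 3 at 0.0471; all 3 falling probes had higher input DNA in DBP arrays. At the gene level 0 of 227 passed by limma, with 15 at unadjusted p below 0.05 and a smallest adjusted p of 0.628. Without the probes of changed input 0 probes passed by limma. The replicate block and the immunoprecipitated channel alone each gave 0 probes, and the normexp correction gave 16, all lower. Leaving out 1 replicate gave 1 probe (control 3 or any DBP replicate), 2 (control 2) or 3 (control 4).

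PolII at GD15 asks whether transcription itself shifts with DBP. The genes of smallest p were Zswim3_predicted, with 0.38 ± 0.45 in control (n = 4) and -0.58 ± 0.38 in DBP testes (n = 3), the proton pump subunit Atp6ap1, with -1.0 ± 0.51 and -0.05 ± 0.27, and LOC680551, with -0.72 ± 0.34 and 0.04 ± 0.37. Fabp3, a fatty acid binding protein, stood at -0.26 ± 0.29 and 0.19 ± 0.05. Of 227 genes 0 passed by limma, with 22 at unadjusted p below 0.05 (19 higher, 3 lower) and a smallest adjusted p of 0.293. With the replicate block 4 genes passed (2 higher, 2 lower), although replicate numbers gave no sign of a pairing of control with DBP arrays. Of 12934 probes 0 passed, with 738 at unadjusted p below 0.05; the smallest were at Psma6 (4.18) and Fabp3 (4.22), both at an adjusted p of 0.0624.

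Insl3, the Leydig cell hormone of testis descent, had a lower ratio in GD15 DBP testes with every antibody: -0.54 with SF1, -0.55 with CBP, -0.56 with PPARA and -0.43 with PolII. None of these passed by limma (adjusted p = 0.457, 0.628, 0.447 and 0.505; unadjusted p = 0.0466, 0.00637, 0.0293 and 0.0325). Input DNA at Insl3 was 1.60 to 1.90 log2 units above the array median in the 16 control arrays and 2.10 to 2.30 in the 16 DBP arrays, while immunoprecipitated DNA averaged 1.5 in both. The higher input lay at 5 of the 22 Insl3 probes, on chromosome 16 from 18890946 to 18891671, that is 845 to 1518 bp downstream of the start. Without the probes of changed input the differences were -0.04, -0.17, -0.33 and 0.02.

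**Figure D3:**
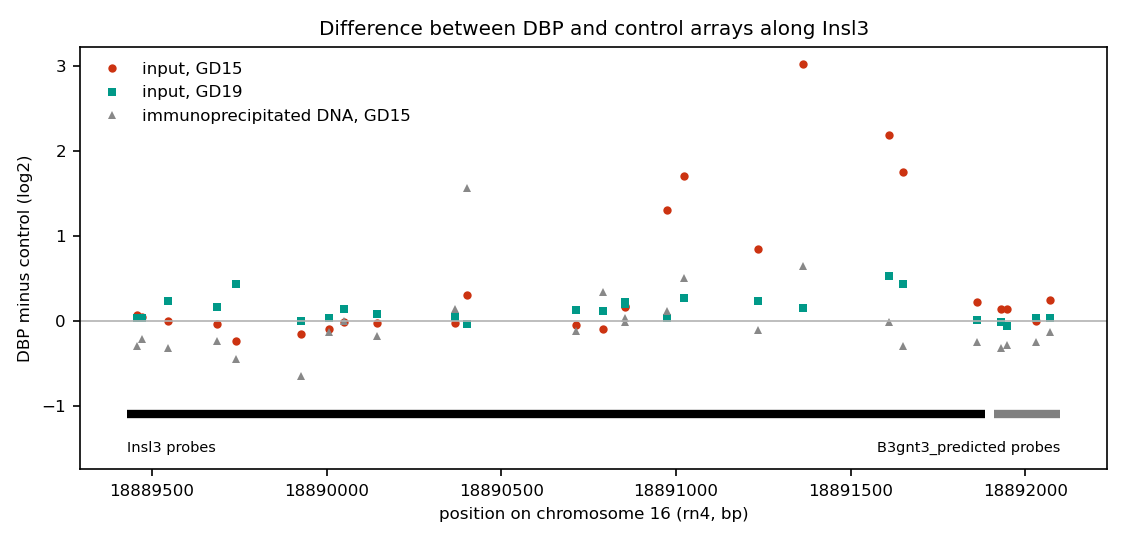
Difference between DBP and control arrays (log2) at each probe of Insl3 and B3gnt3_predicted along chromosome 16, as the mean over the 4 antibodies, for input DNA at GD15 and GD19 and for immunoprecipitated DNA at GD15; bars mark the probes of each gene. Input at GD15 reaches 3.02 within Insl3.

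Input DNA differed between treatments at GD15 in short stretches across the array. At 136 probes in 69 stretches near 60 genes it was more than 1 log2 unit higher in DBP testes, with a mean of 1.80 and a median stretch length of 60 bp, and 129 of the probes were higher in each of the 16 DBP arrays than in any of the 16 control arrays. At 3 probes it was lower by that much. At GD19 the numbers were 0 higher and 2 lower. The Prdx2 stretch was at 1.03 to 1.42 in GD15 control and 5.07 to 5.22 in GD15 DBP arrays, against 1.12 to 1.33 and 1.31 to 1.49 at GD19. The immunoprecipitated channel was 0.54 higher at the 136 probes. These numbers are counts of differences, without a test of significance. The 16 arrays of a treatment are not 16 independent input samples. Input DNA correlated at a median r of 0.99 between replicates of a group, against 0.96 (range 0.91 to 0.99) over all pairs of arrays. Arrays may have shared an input DNA, which these close values cannot settle. The full separation of 16 from 16 arrays may thus rest on far fewer input samples, possibly 1 for each treatment. The same holds for the input ranges at Insl3 and Prdx2.

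**Figure D4:**
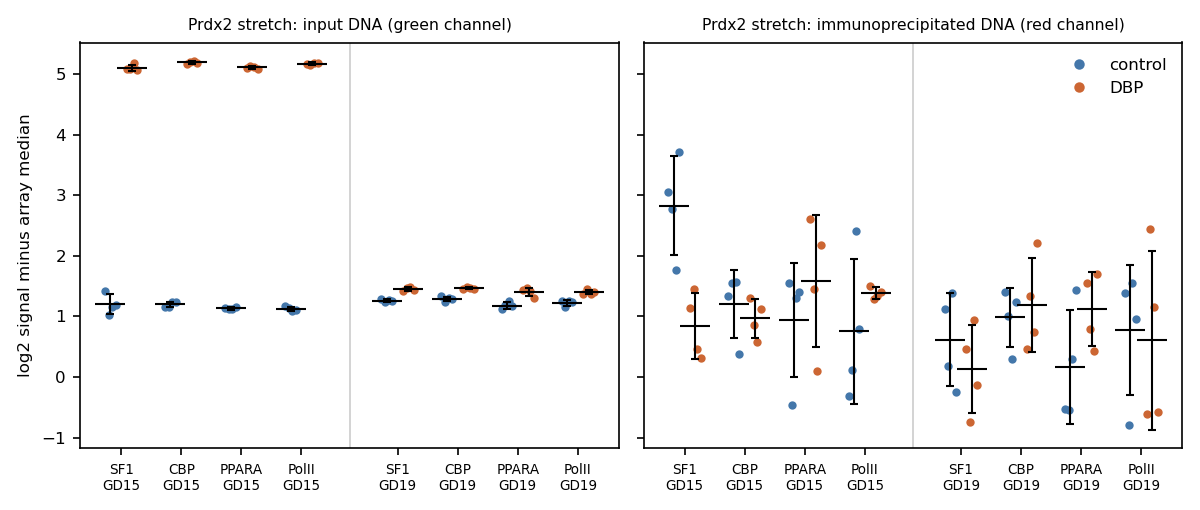
Signal of input DNA (left) and immunoprecipitated DNA (right) at 3 Prdx2 probes on chromosome 19, in log2 units above the array median, per array (points; bar and whiskers, mean and SD; blue, control; orange, DBP). Input in GD15 DBP arrays lies at or above 5.07 while GD15 control arrays stay at or below 1.42.

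PPARA at GD19 had mostly higher gene values with DBP, chiefly on arrays 3 and 4. The median difference over all genes was 0.31 log2 units after centring, and of 37 genes at unadjusted p below 0.05, 36 were higher. For the single DBP arrays 1 to 4 the median differences from the control mean were 0.05, 0.08, 0.47 and 0.60. Arrays 3 and 4 also had lower immunoprecipitated signal (medians of 473.3 and 606.4, against 823.8 and 879.7 on arrays 1 and 2) and lower ratio medians before centring (-0.526 and -0.506, against 0.072 and 0.103). The smallest p-values belonged to RGD1306809_predicted (-0.74 ± 0.72 in control and 0.54 ± 0.26 in DBP testes), Srebf2, the transcription factor of cholesterol synthesis (-0.35 ± 0.07 and 0.35 ± 0.34), and Ccdc134 (-0.20 ± 0.40 and 0.72 ± 0.70; SD, n = 4 each). Among steroidogenic genes Cyp11a1 stood at -0.34 ± 0.22 in control and 0.23 ± 0.40 in DBP testes. By limma 0 of 227 genes passed (smallest adjusted p = 0.174), and of 12972 probes 0 passed, with 891 at unadjusted p below 0.05; the smallest was at Sc4mol, of sterol synthesis (-5.37, adjusted p = 0.231). The spread of the log2 ratios was wider on the DBP arrays (SD 1.64 ± 0.04 against 1.42 ± 0.07; exact two-sided permutation p = 0.0286, adjusted 0.114). In 1 fit of all arrays, which shares the spread over the groups, 14 genes passed, all higher, among them Srebf2 (0.70, adjusted p = 0.0111).

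SF1 at GD19 had lower values in DBP testes for the genes of smallest p: Pygl, glycogen phosphorylase (0.22 ± 0.36 in control, -0.65 ± 0.33 in DBP), Slco1b2 (0.13 ± 0.40 and -0.57 ± 0.21) and Mlycd (-0.13 ± 0.17 and -0.64 ± 0.16; SD, n = 4 each). By limma 0 of 227 genes passed (smallest adjusted p = 0.239), with 15 at unadjusted p below 0.05, all lower. Of 12972 probes 0 passed, with 857 at unadjusted p below 0.05; that at Lcat, lecithin-cholesterol acyltransferase, had a difference of -3.16 and an adjusted p of 0.135.

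CBP at GD19 gave small differences. Cyp4a2, a fatty acid hydroxylase, stood at -0.43 ± 0.17 in control and 0.11 ± 0.11 in DBP testes, Apoe, the lipoprotein ligand, at 0.11 ± 0.05 and -0.23 ± 0.12, and Trib3, a stress-induced pseudokinase, at 0.05 ± 0.03 and 0.35 ± 0.18 (SD, n = 4 each). In each of the 3 genes the control and DBP samples did not overlap, as happened for 13 of 227 genes (5.7%, against 2.86% by chance). Of 227 genes 0 passed by limma, with 11 at unadjusted p below 0.05; the adjusted p was 0.126 for Cyp4a2. Of 12971 probes 0 passed, with 638 at unadjusted p below 0.05, and those of smallest p were at Ca2, carbonic anhydrase 2 (-2.98 and -3.12, adjusted p = 0.333).

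PolII at GD19 showed its smallest p-values at MGC94192 (0.47 ± 0.68 in control, -0.53 ± 0.48 in DBP), Fgb, fibrinogen beta (0.35 ± 0.32 and -0.22 ± 0.20), and Scp2, a sterol carrier protein (0.07 ± 0.33 and -0.55 ± 0.34; SD, n = 4 each). Of 227 genes 0 passed by limma, with 9 at unadjusted p below 0.05 and a smallest adjusted p of 0.832. Of 12972 probes 0 passed, with 797 at unadjusted p below 0.05; the smallest p was at Lnpep, an aminopeptidase (3.1, adjusted p = 0.0722).

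The effect of DBP differed between the days at Ada with SF1. Its difference between DBP and control was 0.78 at GD15 and -0.44 at GD19, a change of -1.22 (SE 0.26), over 26 probes on chromosome 3, 154636326 to 154638441, which lie 22226 to 24282 bp downstream of the start. Perilipin (Plin) at -0.93 and cytochrome c (Cycs) at -0.87 came next with SF1. With CBP the smallest p-values were at Eif1a (-1.31), Lnpep (-0.86) and B3gnt3_predicted (0.95), with PPARA at RGD1306809_predicted (1.43), MGC94192 (2.19) and Eef2 (1.23), and with PolII at Yc2 (-0.91), Cyp4b1 (-1.01) and Scp2 (-0.84).

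By limma Ada passed at an adjusted p of 0.0352, the only gene of 227 with SF1, where 18 had an unadjusted p below 0.05. The other antibodies had 0 genes past the threshold by limma, with 15 (CBP), 24 (PPARA) and 11 (PolII) at unadjusted p below 0.05. The Ada call ended under the normexp correction (-0.63, adjusted p = 0.298), with the immunoprecipitated channel alone (-0.95, adjusted p = 0.143), and without GD15 DBP replicate 1, 2, 3 or 4, GD19 control replicate 1, 2 or 4, or GD19 DBP replicate 1, 3 or 4.

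The panel of testis genes fixed beforehand had 10 members on the array: Star, Cyp11a1, Cyp17a1, Scarb1, Insl3, Inha, Nr0b1, Hmgcs1, Fabp3 and Crabp2, and 0 of them passed by limma in any of the 8 comparisons. Beyond Insl3, the members at unadjusted p below 0.05 were Fabp3 with PolII at GD15 (0.45, limma adjusted p = 0.505) and Cyp11a1 with PPARA at GD19 (0.57, limma adjusted p = 0.305). Star, the cholesterol carrier that limits steroid synthesis, differed by 0.08 (SE 0.31) with SF1 at GD15 and by -0.42 (SE 0.28) with PolII at GD19. Cyp17a1 differed by 0.16 (SE 0.23) and 0.05 (SE 0.20) in the same comparisons. The starts of Star and Cyp17a1 were not tiled, so these values come from probes downstream.

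No functional group passed as a set, as measured over the tiled probes. The steroidogenic list had 8 measured genes, cholesterol synthesis and uptake 9, fatty acid metabolism and PPAR targets 28, Sertoli cell genes 6, redox and xenobiotic response 5, retinoid signalling 3, and immediate early factors 2 (Btg1 and Junb). The transcription start was tiled for 4 steroidogenic, 5 cholesterol, 14 fatty acid, 5 Sertoli, 2 redox, 3 retinoid and 2 immediate early genes. For the other members, signal at the start was not measured. With PPARA at GD19, 7 of 8 steroidogenic, 8 of 9 cholesterol, 24 of 28 fatty acid, 6 of 6 Sertoli, 5 of 5 redox, 3 of 3 retinoid and 2 of 2 immediate early genes were higher, with list medians of 0.40, 0.33, 0.30, 0.44, 0.41, 0.10 and 0.16 beside the array-wide 0.31. Of 56 list tests 0 passed with camera, with camera at an estimated correlation or with fry in either form, and 0 had an unadjusted camera p below 0.05. Over all genes 0 list members passed; adjusted over the list alone 2 did, both with CBP at GD19, Apoe (-0.34) of the cholesterol list and Cyp4a2 (0.54) of the fatty acid list. In 12 of the 56 tests the list median and the camera direction, which is relative to the other genes, differed in sign, among them the fatty acid, retinoid and immediate early lists with PPARA at GD19; the median and the mean differed in sign in 3. The marker genes of other tissues Cyp21a1, Apoa2 and Ttr did not pass by limma in any comparison; the smallest unadjusted p was that of Ttr with PolII at GD15 (0.57, limma adjusted p = 0.472).

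Across genes, DBP effects of different antibodies on the same day correlated with a median r of 0.08 (range -0.17 to 0.33, 12 pairs), those of the same antibody on both days with -0.15 (4 pairs), and the others with -0.04 (12 pairs). The input channel alone gave a median of 0.89 on the same day, and the immunoprecipitated channel alone gave 0.20. Genes are not independent replicates, and these 28 correlations are descriptive.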

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

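The tests of both channels and of slide row at Prdx2 and Insl3, of the share of spot noise, of the replicate numbers and of slide or antibody preparation were chosen only after the result was seen; the tests of fragment sampling, of GC content and of the splits of the samples were not.

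Ratios at Prdx2 and Insl3 were lower in GD15 DBP testes, and the input channel, which the comparisons use only as a reference, showed its own difference between treatments: 136 probes were more than 1 log2 unit higher in DBP arrays, input at the Prdx2 stretch was 3.98 higher and input at Insl3 was 0.50 higher. For the gene mean of Insl3 a loss of immunoprecipitated DNA is argued against: it made up -3.8% of the fall of the ratio and the input difference 96.2%. At single Insl3 probes the immunoprecipitated channel differed by -0.64 (at -202 bp from the start) to 1.57 (at 270 bp). A loss at part of the gene, such as upstream of the start, therefore stays open. A loss is also argued against at the Prdx2 stretch with CBP, PPARA and PolII (mean difference 0.35). With SF1 the immunoprecipitated channel differed by -1.99 there, between the bounds set, so a loss beside the higher input stays open. The input differences of the genes were alike on the arrays of the 4 antibodies (lowest r = 0.85 across genes), which is consistent with 1 input DNA used for all of them. Over the 136 probes, more of these stretches in the DBP chromatin itself cannot be told apart from DNA that entered the input alone. The immunoprecipitated channel rose there by 30% of the input difference, between the bounds set for either. At the Prdx2 stretch input rose by 3.9 to 4.05. The immunoprecipitated channel differed there by -1.99 (SF1), -0.24 (CBP), 0.64 (PPARA) and 0.66 (PolII). At the 5 Insl3 probes of higher input, input rose by 1.31 to 3.02 and the immunoprecipitated channel differed by -0.29 to 0.65. At these Prdx2 and Insl3 probes the values argue against more of the DNA in the DBP chromatin. A slide row acting alike on both days, whose slides had the same layout, is argued against at the Prdx2 stretch, where the input difference at GD19 was 4.8% of that at GD15, but cannot be told apart at Insl3 (32%, between the bounds set); an effect of DBP on the DNA recovered as input, and amplification, stay open and untested.

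Replicate log2 ratios agreed poorly. Noise of single spots is argued against, as spots of 1 probe held 4.1% of the variance between replicates. Deviations of neighbouring probes 60 to 150 bp apart correlated at 0.46 and those 1500 to 3000 bp apart at 0.01, which is consistent with chance sampling of few DNA fragments before amplification as a candidate explanation. Litter differences shared by the immunoprecipitations of one chromatin sample would make same-numbered arrays of different antibodies more alike; their median correlation exceeded that of other arrays by 0, but the labels do not say that the numbers follow the chromatin samples, so this cannot be told apart.

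PPARA signal was higher near transcription starts in control arrays. GC content may account for it, since -11.4% of the difference was left after probes were matched for GC content. Slide or antibody preparation cannot be told apart from a property of PPARA itself, because each antibody had its own slides: the lower of the PPARA slides stood at 0.19 and the other slides at 0.00 to 0.08. Binding of PPARA at starts was not tested in any other way.

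The effect of DBP on Ada with SF1 differed between the days by -1.22 log2 units, in a test of the difference itself (limma adjusted p = 0.0352), and was 0.78 at GD15 and -0.44 at GD19. The call ended under normexp (limma adjusted p = 0.298), with the immunoprecipitated channel alone (0.143) and when certain single replicates were left out. Input DNA at Ada also differed between treatments on the SF1 arrays, by -0.11 at GD15 and 0.17 at GD19.

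Single samples far from the other 3 of their group appeared in 12 of 195 groups, where chance gives about 9.8. With SF1 at GD19 these were Cyp11a1 in DBP sample 3 (-0.02, others -0.33 to -0.29) and Cyp17a1 in DBP sample 2 (-0.24, others -0.05 to -0.02). With SF1 at GD15 they were Cyp11a1 (0.19, others -0.51 to -0.39) and Nr0b1 (-0.67, others -0.38 to -0.33) in control sample 4, Hmgcs1 in DBP sample 4 (0.18, others -0.22 to -0.16) and the array median before centring in control sample 2 (-0.01, others 0.08 to 0.09). With CBP at GD15 they were Inha in control sample 1 (-0.64, others -0.03 to 0.02), Hmgcs1 in DBP sample 4 (-0.04, others 0.10 to 0.11) and the array median before centring in control sample 4 (-0.11, others 0.07 to 0.10). With PPARA at GD19 they were Nr0b1 in DBP sample 2 (-0.60, others 0.21 to 0.29) and the difference near starts in control sample 3 (0.10, others 0.18 to 0.19), and with PolII at GD19 the difference near starts in control sample 2 (0.26, others -0.02 to 0.01).

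Other divisions of the same samples into groups of the real sizes show which counts chance can give. Taken singly, and without adjustment over the 20 counts examined, the share of splits was below 0.05 for the 35 SF1 probes and the 2 PPARA genes at GD15. There only the real split, 1 of 35, gave as many (highest of the others 1 in each case), and 1 of 35 is the smallest share possible. A low share does not say that antibody signal changed with treatment. The 10 falling SF1 probes had higher input in DBP arrays, and slide row coincides with treatment. For the interaction gene Ada with SF1, 4 of 100 splits, drawn at random with the real one included, gave 1 gene and none gave more. With 100 draws this share is too coarse to be told apart from 0.05, so chance is not excluded there. Over all 20 counts chance is not excluded, and each of these calls changed when single replicates were left out. It is not excluded for the 5 CBP probes at GD15, as 3 of 35 splits gave as many and the highest other gave 15, which is 3 times the real count; this may point to a structure of the samples apart from treatment, which was not tested. For comparisons with a real count of 0, each split gave as many (35 of 35, or 100 of 100 for the interactions with CBP, PPARA and PolII). There the highest other split gave 0 genes with SF1 and CBP at GD15, 1 gene and 4 probes with PolII at GD15, 16 probes with PPARA at GD15, 2 genes and 17 probes with SF1 at GD19, 1 gene and 6 probes with CBP at GD19, 1 gene and 0 probes with PPARA at GD19, and 1 gene and 7 probes with PolII at GD19. For the interactions it gave 1 (CBP), 1 (PPARA) and 2 (PolII) genes.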

How the results depend on the processing

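The tests restricted to probes near starts or without probes of changed input, those with array weights, low-signal arrays left out or both arrays of the repeated pair, and, for probes, interactions and correlations of effects, those of single channels and (for probes) of left-out replicates were chosen only after the result was seen. No called value changed sign, while 173 values without a call did, among them 36 with the window of 3 probes, 21 near starts and 17 with normexp and loess. Of 2063 values of named genes under the alternatives, 1896 kept their side of the threshold or moved by less than the replicate spread, 139 moved by more, 13 passed only in the alternative and 15 no longer passed; the dim-probe filter and the deposited value table changed no count of calls. Causes of the changes were not tested, except that omitted probes cannot be called.

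Under normexp, SF1 at GD15 gave 2 genes (Cd36 and Prdx2) and 23 probes (1 higher and 22 lower, against 25 and 10), CBP at GD15 16 probes, PolII at GD15 4 probes, the SF1 interaction 0 genes, and enrichment 1 gene for SF1 and 0 for PPARA at GD15. Normexp with loess gave 1 gene for CBP at GD15 (Insl3, -0.44, adjusted p = 0.0424). A common spread gave 2 genes for SF1 at GD15 (Cd36 among them), 1 for PPARA at GD15 and 5 for the SF1 interaction. For PPARA at GD15 array weights gave 1 gene. The window of 3 probes and the probes near starts gave 0 there, but neither holds a value for B3gnt3_predicted, and the probes near starts hold none for Zswim3_predicted, so there those genes could not be called. One fit of all arrays gave 14 genes for PPARA at GD19, and for PPARA at GD15 2 genes, neither of which was B3gnt3_predicted or Zswim3_predicted. The replicate block gave 4 genes for PolII at GD15, 2 probes for SF1 at GD15 and 0 for CBP at GD15, and it moved no other count of calls by over 1.5 times. The immunoprecipitated channel alone gave 0 genes and 4 probes for PPARA at GD15, 8 probes for SF1 and 0 for CBP at GD15, and 0 genes for the SF1 interaction. Without the probes of changed input SF1 at GD15 had 7 probes, all higher, and CBP 0. Array weights gave 71 probes for SF1, 11 for CBP and 6 for PolII at GD15. Without the low-signal array CBP at GD15 had 3 probes, and with both arrays of the repeated pair PolII at GD15 had 31. The correlation of effects on the same day moved from 0.08 to 0.20 with the immunoprecipitated channel and 0.89 with the input channel alone.

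Leaving out 1 replicate gave 0 to 3 genes for PPARA at GD15, 0 to 1 for PPARA at GD19, PolII at GD15 and PolII at GD19, 0 to 6 for the SF1 interaction, 0 to 1 for the PPARA interaction, and 0 for the other gene counts. It gave 3 to 147 probes for SF1 at GD15, 1 to 5 for CBP at GD15, 0 to 4 for SF1 at GD19, 0 to 1 for CBP and PolII at GD19 and 0 for the others. Enrichment in controls ran from 0 to 5 genes for PPARA at GD15 and 0 to 3 for PolII at GD19. Immunoprecipitated signal stood well above background at 90.4% or more of the spots of each array; what limits the number of calls was not tested.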

Other observations

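The enrichment of single genes in DBP arrays and the placement of the tiles, both described here, were examined only after the data had been seen, though the prediction for the tiles was set before its result.

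SF1 arrays of GD15 DBP testes carried signal over a pair of neighbouring genes on chromosome 10. Polg2_predicted (96126376 to 96131916) and Ccdc45 (96132022 to 96133889) stood at 0.55 ± 0.21 and 0.50 ± 0.57 above the array median on DBP arrays, and at 0.63 ± 0.37 and 0.79 ± 0.84 on the control arrays (SD, n = 4 each). The difference between treatments was -0.08 (SE 0.21) and -0.29 (SE 0.40). Sfrs3_predicted, a splicing factor (0.59 ± 0.35, control 0.64 ± 0.16), and Ech1, an enzyme of fatty acid oxidation (0.51 ± 0.31, control 0.50 ± 0.47), stood above the median on the same DBP arrays. By limma the enrichment had an adjusted p of 0.00512 for Polg2_predicted, 0.0466 for Ccdc45, 0.00714 for Sfrs3_predicted and 0.0101 for Ech1. At GD19 Polg2_predicted was not raised with SF1 (-0.16 ± 0.28, n = 8, control and DBP together) or CBP (-0.07 ± 0.15, n = 8).

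PPARA arrays of GD19 DBP testes had 7 genes above the enrichment threshold, at unadjusted p below 0.05 for 30 genes by limma. Gene values as a whole were higher there than the control mean, by a median of 0.47 and 0.60 on DBP arrays 3 and 4 against 0.05 and 0.08 on arrays 1 and 2, so these genes are not set apart from an array-wide shift. Amh, the Sertoli cell hormone that makes the Müllerian ducts regress, stood at 0.95 ± 0.36 (control 0.35 ± 0.34), the kinase gene Akt1 at 0.90 ± 0.40 (control 0.24 ± 0.08) and Gpx4, the lipid peroxide reducing enzyme, at 0.84 ± 0.54 (control 0.43 ± 0.17; SD, n = 4 each). B3gnt3_predicted stood at 1.11 ± 1.28 there, against 0.36 ± 1.11 in control. MGC94192, Sbno2 and Smarcd1_predicted followed at 0.88, 0.81 and 0.80. The remaining 6 groups of DBP arrays had 0 genes by limma, with 1 gene at unadjusted p below 0.05 for CBP at GD19 and 1 for PolII at GD19, and 0 for CBP, PPARA and PolII at GD15 and SF1 at GD19.

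A hypothesis of this re-analysis is that tiles were placed from the lower coordinate of each gene whatever its strand, which could leave starts of minus-strand genes uncovered. Of genes on the minus strand 73% had no probe within 500 bp of the start, against 26.3% on the plus strand, just short of the bounds set for the test, so it stays undecided.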
